A study of Mus musculus with 6 samples.

How the data were processed

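The data were gene-level RNA sequencing values of 6 mouse lung endothelial cell libraries, 3 from mice on ND and 3 from mice on HFD, each from 500 cells of a separate animal. Per the labels' protocols, RNA was primed with oligo(dT), reverse transcribed with template switching, amplified by PCR and sequenced on a NextSeq 550 instrument, and no molecular identifiers are mentioned. Priming at the poly(A) tail favours polyadenylated transcripts, and amplification from 500 cells can add spread between libraries that depth does not remove. Per the submitters' processing notes, cutadapt, FastQC 0.11.7, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, HTSeq 0.6.1 and DESeq2 were used with the GRCm38 build, and the notes as used here give no role or order for them. The gene annotation behind the counts, and whether counting used strand, are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

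The authors deposited 1 table of 23345 genes with a column per library, and its values are a normalized signal, namely gene read counts divided by a size factor of each library. Within each column every value was a whole multiple of the value of 1 read, which was 0.720 in the deepest and 1.19 in the shallowest library. By that step 100% of the values came out whole within a tolerance of 1e-06, with a largest deviation of 1.34e-09, so the reads per gene and the depth of each library could be recovered. The depths were 17.2 M reads in ND 1, 14.5 in ND 3, 13.8 in ND 4, 18.8 in HFD 2, 22.2 in HFD 4 and 27.9 in HFD 5. All HFD libraries were deeper than all ND libraries. The 10 genes with most reads took 7.86% to 9.08% of a library. All pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 96.2 to 231, so each was counted as 1 replicate. Columns were matched to samples by diet letter and mouse number, and 0 columns of per-sample values were left unmatched.

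Values were tested as log2(normalized count + 1) over the 15655 genes with a mean of at least 10 normalized counts. A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. HFD minus ND was tested two-sided with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, no covariates and Benjamini-Hochberg adjustment at 0.05. Where every library of a diet had 3 reads or fewer, the fold change depends on the pseudocount, so the ratio of summed reads scaled by the size factors is given with a 95% exact conditional interval instead.

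Before the data were examined, the design, 40 gene lists, the rule for named genes and all alternative settings but 2 were fixed. The lists covered endothelial subtypes, other lung and blood cell types, metabolism, responses, functions and RNA quality. Of these, 39 were tested with limma's camera at a preset correlation of 0.01, and the list of sex-linked genes was left out. Camera was repeated with an estimated correlation, and fry was run beside it. Within each list, adjusted p values were also computed over the list alone. List levels per library are means of log2 values, compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. The rule for named genes was as follows. Up to 10 genes per direction past the threshold were to be named, with no overlap between the diets, a mean of at least 50 and a symbol other than a clone name, and, where fewer passed, the 5 of smallest p per direction under the same count and symbol conditions. Added to these were the 4 members of smallest p of each list that passed camera, up to 2 members of the other lists that passed over all genes or over the list alone, and a set of genes fixed whatever their values, 2 of which are not reported here. The rule as applied named 63 genes with a value.

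Positions are from the GENCODE M21 annotation of GRCm38. Of 23345 symbols, 23203 matched by symbol, 2 by another symbol and 140 not at all, and 62 of the 63 named genes had a single match, the exception being Aldoa. All 62 are annotated as protein coding. Other genes overlap more than 10% of the exonic bases of 9 named genes and more than 25% of those of 4.

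The tests were checked on simulated counts with the real means and depths, 200 genes changed by known folds and the spread of the real libraries, over 14929 genes. There limma called 0% of the 2-fold, 14.9% of the 4-fold and 53.0% of the 8-fold changes of HFD against ND and 0 unchanged genes. DESeq2 called 10.4%, 46.3% and 75.8%, with 105 unchanged genes called. With the dispersion divided by 10, over 15456 genes, limma called 55.2%, 89.6% and 98.5% and 9 unchanged genes, and DESeq2 73.1%, 97.0% and 98.5% and 48 unchanged genes. Camera called 0 of 20 simulated lists of 36 genes with no shift and 20 of 20 with a shift of 1 log2 unit, for genes drawn independently of each other.

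Alternatives were pseudocounts of 0.5 and 5, a minimum mean of 1 or 50 or no filter, TMM scaling, equal column totals, quantile normalization, sample quality weights, a robust fit, no trend, other thresholds and leaving out each library in turn. On the recovered whole reads, the quasi-likelihood test of edgeR 4.0.16 called 0 genes and DESeq2 1.42.0 called 272. DESeq2 gave no adjusted p for 1708 genes, which stayed without one. Limma-voom on the whole reads, which called 0 genes, and thinning of all libraries to the depth of the shallowest were the 2 alternatives added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.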

Results

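Messenger RNA was profiled in endothelial cells, the cells that line blood and lymph vessels, taken from the lungs of C57BL/6JOlaHsd mice. The mice had been kept for 12 weeks on a normal diet (ND) or on a high-fat diet (HFD), which is used to bring on weight gain and metabolic disease. Dissociated lung cells were depleted of cells carrying CD16/CD32, receptors typical of white blood cells, enriched with beads against ICAM-2, an endothelial surface protein, and kept on collagen I before RNA was extracted. The series held 3 ND libraries (mice 1, 3 and 4) and 3 HFD libraries (mice 2, 4 and 5), each made from 500 cells of a separately numbered animal. The number 4 occurs in both diets and names different mice, so no ND mouse was paired with an HFD mouse. The values were gene read counts that the authors had divided by a size factor per library. The whole reads behind them came to 17.2, 14.5 and 13.8 M reads in ND 1, ND 3 and ND 4, with a mean of 15.1 ± 1.81 M reads (SD, n = 3). The HFD libraries were deeper, with 18.8, 22.2 and 27.9 M reads in HFD 2, HFD 4 and HFD 5 and a mean of 22.96 ± 4.59 M reads (SD, n = 3).

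The transcripts targeted by the cell selection were measured in every library. Icam2 had 14073 to 25569 normalized counts. Fcgr3, which encodes CD16, had 0 reads in 4 libraries, which allows up to 3.54 normalized counts in ND 1, 3.21 in ND 3, 2.42 in HFD 4 and 2.16 in HFD 5. It had 137 normalized counts in ND 4 and 103 in HFD 2. Fcgr2b, which encodes CD32, had 1.94 to 5.94 normalized counts. PCR reads without molecular identifiers are not independent molecules, so such limits and all counting intervals given here cover counting error only.

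The comparison asked which transcripts of lung endothelial cells differed between HFD and ND mice. Lung endothelial cells of HFD mice had more transcript from genes of fatty acid use and from genes induced by interferon, each taken as a group, than those of ND mice. Both calls came from a set test with a preset correlation between genes and were lost otherwise, at an adjusted p = 0.826 with an estimated correlation. Of 36 tested genes of fatty acid use, 27 were higher in HFD, and the mean level of the group rose by 0.66 log2 units, from 8.25 ± 0.16 to 8.91 ± 0.05 (SD, n = 3). Of 37 tested interferon-response genes, 33 were higher in HFD, and the mean level rose by 0.71 log2 units, from 9.34 ± 0.16 to 10.05 ± 0.32 (SD, n = 3). In both groups each HFD library lay above each ND library. Less even shifts past the same threshold were a rise of antigen presentation and glycolysis genes and a fall of lymphatic, mural, epithelial, YAP-target and mitochondrially encoded genes, with libraries of the diets that overlapped. These 7 calls were lost too, at an adjusted p = 0.826 with an estimated correlation.

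**Figure D1:**
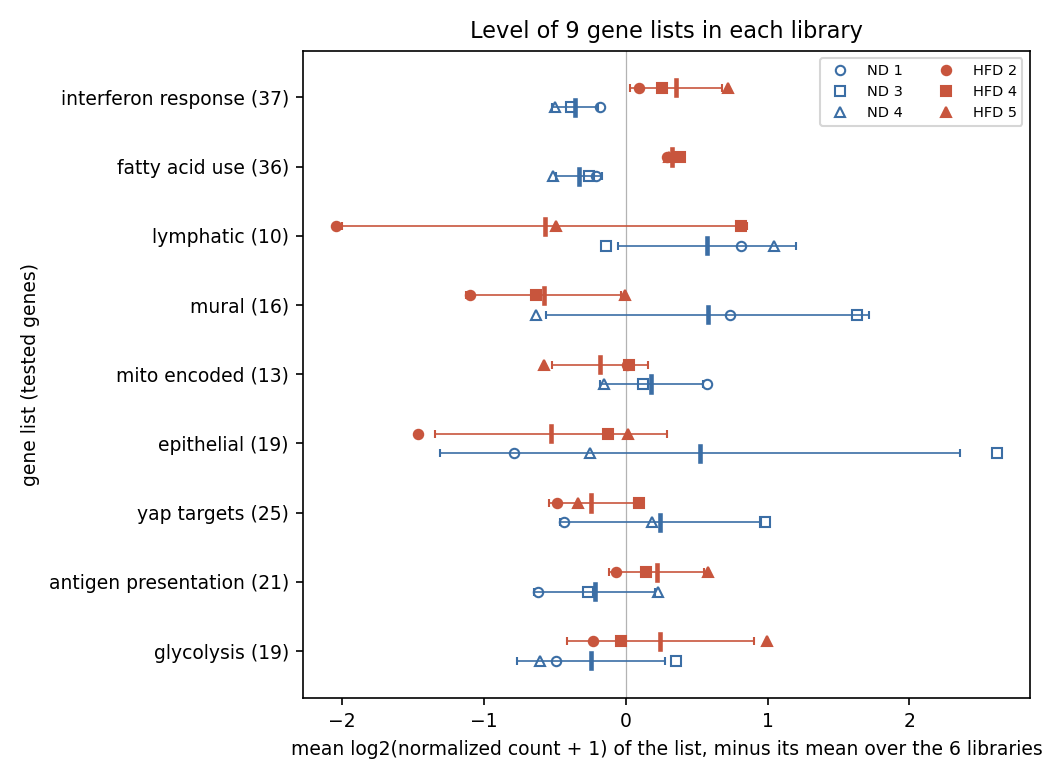
Mean log2(normalized count + 1) of each of 9 gene lists in each of the 6 libraries, drawn as the difference from the list's mean over the libraries, with the number of tested genes after the name. Open blue symbols are ND and filled red symbols HFD libraries, vertical marks are group means and horizontal bars are 1 SD (n = 3). All 3 HFD libraries lie above all 3 ND libraries for the interferon response and fatty acid use lists, and the diets overlap in the other 7.

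The groups were tested against all other genes with camera at a preset correlation of 0.01. Of 39 lists fixed before the data were examined, 9 passed an adjusted p of 0.05, 4 of them higher and 5 lower in HFD. The adjusted p was 0.000836 for interferon response and 0.0356 for fatty acid use, against 0.0364 to 0.0495 for the other 7. None of the 9 calls held when the correlation between genes was estimated from the 6 libraries, since each then had an adjusted p = 0.826 with an estimated correlation. The estimate was 0.0103 for fatty acid use, close to the preset 0.01, 0.119 for interferon response and 0.825 for mitochondrially encoded genes. The loss for fatty acid use, whose unadjusted camera p went from 0.00182 to 0.0360, did not come from a higher correlation. With an estimated correlation camera uses the 4 residual degrees of freedom of the 6 libraries, which by itself raises p. A lost call therefore does not show by itself that correlation between the genes of a list had produced it. The fry test, which asks whether the genes of a list move one way without comparing them with other genes, called 0 lists, with a smallest adjusted p of 0.0583 for fatty acid use. An exact two-sided permutation test of the list levels, 3 mice against 3, cannot go below 0.1, and it gave that smallest value, p = 0.1, for 6 of 39 lists, where chance gives 10%. These were the 2 leading lists and 4 that did not pass camera, namely pan-endothelial, lung capillary, cell cycle and insulin signalling. Camera calls numbered 3 under equal column totals, 2 higher and 1 lower, 3 with sample quality weights, 2 higher and 1 lower, and 4 under quantile normalization, 2 higher and 2 lower. The balance of directions depended on the filter and the libraries, with 6 higher and 2 lower at a minimum mean of 1, 6 and 1 with no filter, 3 and 3 at a minimum mean of 50, 2 and 3 without ND 1, 4 and 0 without ND 3 and 2 and 2 without HFD 5. Equal totals moved the median log2 fold change of all tested genes from 0.05 to −0.06. The 3 lists called under equal totals were among the 9, namely interferon response at a mean of 0.60, fatty acid use at 0.55 and mitochondrially encoded genes at −0.48.

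No single gene passed the threshold in the limma test of 15655 genes, in which the smallest adjusted p was 0.276. At an unadjusted p under 0.05 there were 1240 genes, 870 higher and 370 lower in HFD. The values of the diets did not overlap for 2200 genes, or 14.1% of those tested, where chance gives 10%. On the same genes as whole reads, the quasi-likelihood test of edgeR called 0 genes, with 1462 at an unadjusted p under 0.05, and limma-voom called 0, with 1311. DESeq2 called 272, of which 169 were higher and 103 lower in HFD, and 123 of the 272 had 3 reads or fewer in some library. The median standard error of a log2 fold change was 0.75, and 0.38 among genes with a mean of at least 500 normalized counts. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.813 to 0.827 within HFD, 0.772 to 0.792 within ND and 0.781 to 0.802 between diets. The principal component that separated the diets was the second and held 21.9% of the variance, against 23.3% for the first. Components 3, 4 and 5 held 19.4%, 18.5% and 16.9%, so the variance was spread almost evenly and the second did not stand out.

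The genes of smallest p in the list of fatty acid use were Acaa2, Ucp2, Fabp4 and Plin2. Acaa2, the thiolase of the last step of mitochondrial β-oxidation, had 679 ± 114 normalized counts in ND and 2104 ± 235 in HFD (mean ± SD, n = 3), a log2 fold change of 1.64 ± 0.30 (SE). Ucp2, an inner mitochondrial membrane carrier, had 2464 ± 572 and 6174 ± 626 (1.35 ± 0.25). Fabp4, a cytosolic fatty acid carrier abundant in capillary endothelium and in fat cells, had 774 ± 395 and 3681 ± 1743 (2.29 ± 0.51). Plin2, a coat protein of lipid droplets, had 945 ± 174 and 2675 ± 862 (1.46 ± 0.35). All 4 were higher in each HFD library than in each ND library. Adjusted over the list alone, these 4 genes passed limma at adjusted p = 0.0168, 0.0168, 0.0302 and 0.0361, and over all genes 0 did, at 0.324, 0.338, 0.410 and 0.459. DESeq2 called all 4 over all genes, at adjusted p = 0.00024, 0.0026, 0.0019 and 0.0083, but it also called 105 unchanged genes in simulated counts. The edgeR and limma-voom tests called 0 genes. Of the 36 genes, 9 were non-overlapping and higher and 0 non-overlapping and lower. The median log2 fold change of the list was 0.31, below its mean of 0.66. Larger rises than those of the named genes were those of Acads at 3.96 (3.10 without ND 3), Cpt2 at 3.18 (1.11 without ND 4) and Etfdh at 2.99 (1.42 without ND 3). Lower in HFD were 9 of the 36 genes, among them Acot1 at −1.47 and Ppargc1a at −1.35 (−0.087 without HFD 2). The camera call stood in each fit without 1 library, at an adjusted p of 0.0145 to 0.0492, and was lost at an adjusted p = 0.826 with an estimated correlation. In the GRCm38 assembly with GENCODE M21 genes, Acaa2 lies on chromosome 18 from 74779197 to 74806208 and Ucp2 on chromosome 7 from 100493337 to 100502020. Fabp4 lies on chromosome 3 from 10204088 to 10208576 and Plin2 on chromosome 4 from 86648386 to 86670060.

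Further genes of lipid handling, fixed for naming whatever their values, did not pass over all genes. Cd36, a fatty acid receptor of the cell surface, had a log2 fold change of 0.30 ± 0.26 at 106236 ± 40011 normalized counts in ND and 126422 ± 21607 in HFD, and the fold change was 0.59 without ND 1, 0.06 without ND 3 and 0.17 without HFD 5. Cpt1a, which admits long-chain fatty acids to the mitochondrion, had 1632 ± 221 and 2350 ± 302 (0.53 ± 0.26), with no overlap between the diets. Angptl4, an inhibitor of lipoprotein lipase, had 6.25 ± 5.73 and 26.3 ± 37.1 (1.17 ± 1.34), and its log2 fold change was −0.03 without HFD 5, 0.76 without ND 4, 1.77 without ND 3 and 1.88 without HFD 4. Pdk4, a kinase that restrains glucose oxidation, fell below the filter on low values, with a mean of 3.57 and a highest value of 6.44. The cholesterol synthesis and cholesterol efflux lists did not pass, at adjusted p = 0.613 and 0.617, nor did fatty acid synthesis at 0.774, whose mean log2 fold change of −0.20 and median of 0.46 had opposite signs.

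The interferon-response genes of smallest p were Usp18, Irgm1, Igtp and Gbp2. Usp18, a protease that removes the ubiquitin-like modifier ISG15 from proteins, had 289 ± 151 normalized counts in ND and 1850 ± 606 in HFD, a log2 fold change of 2.80 ± 0.56. Irgm1 and Igtp, interferon-inducible GTPases, had 3106 ± 42.4 against 5228 ± 450 (0.75 ± 0.20) and 2809 ± 298 against 4973 ± 957 (0.81 ± 0.24). Gbp2, a guanylate-binding protein, had 3567 ± 605 and 6129 ± 1236 (0.77 ± 0.25). None passed over all genes, at limma adjusted p = 0.357 to 0.551, and adjusted over the list alone 0 of 37 did, with a smallest adjusted p of 0.0531 for Usp18. Non-overlapping members numbered 7 higher and 1 lower. The camera call stood in each fit without 1 library, at an adjusted p of 0.00110 to 0.0378, and was lost at an adjusted p = 0.826 with an estimated correlation. Usp18 lies on chromosome 6 from 121245906 to 121270917 and Irgm1 on chromosome 11 from 48861968 to 48871683.

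Antigen presentation genes, of which Psmb8, Psmb9 and Tap1 also belong to the interferon list, rose as a group by a mean of 0.44 log2 units, with 16 of 21 higher (camera adjusted p = 0.0495). The call was lost with the correlation estimated (adjusted p = 0.826 with an estimated correlation), and without ND 1, ND 3, HFD 4 or HFD 5, at adjusted p = 0.322, 0.280, 0.141 and 0.163. The mean shift was 0.24 without ND 1 and 0.25 without HFD 5, but 0.66 without ND 4. H2-Ab1, a chain of the major histocompatibility complex class II, had 17104 ± 4171 normalized counts in ND and 33550.0 ± 5651 in HFD, a log2 fold change of 0.99 ± 0.21. It was the single member that passed adjusted over the list alone (limma adjusted p = 0.0438), and it did not pass over all genes (0.392). H2-Eb1 of class II had a log2 fold change of 0.81 ± 0.25, H2-D1 of class I 0.93 ± 0.27 and Tap2, a peptide transporter, 2.35 ± 0.98 (1.28 without ND 1), and none of these passed. Reads of H2 genes can be shared with near-identical family members, so their single values are uncertain. H2-Ab1 lies on chromosome 17 from 34257689 to 34269419. Markers of white blood cells, which also carry class II molecules, were measured beside these genes. The macrophage list had a mean level of 4.09 ± 1.53 in ND and 3.69 ± 0.74 in HFD, and the lymphocyte list 3.22 ± 0.33 and 3.00 ± 0.95 (SD, n = 3).

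Glycolysis genes rose as a group by a mean of 0.49 log2 units, with 16 of 19 higher (camera adjusted p = 0.0495, and adjusted p = 0.826 with an estimated correlation). Aldoa and Eno1, glycolytic enzymes, had 6008 ± 896 against 11217 ± 1827 normalized counts (log2 fold change 0.90 ± 0.21) and 861 ± 261 against 2612 ± 1097 (1.57 ± 0.42), each without overlap between the diets. Pfkl, a phosphofructokinase, had a log2 fold change of 2.38 ± 0.79 and Pkm, pyruvate kinase, 0.98 ± 0.48 (0.63 without ND 4). Adjusted over the list alone 0 genes passed limma, with a smallest adjusted p of 0.0623, and 0 passed over all genes. The list level was 9.32 in HFD 5 against 8.09 and 8.29 in the other HFD libraries. The call was lost without ND 1, ND 4, HFD 4 or HFD 5, at adjusted p = 0.248, 0.204, 0.113 and 0.454. The mean shift was 0.11 without HFD 5 and 0.31 without ND 4, but 0.63 without HFD 4 and 0.79 without ND 3.

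**Figure D2:**
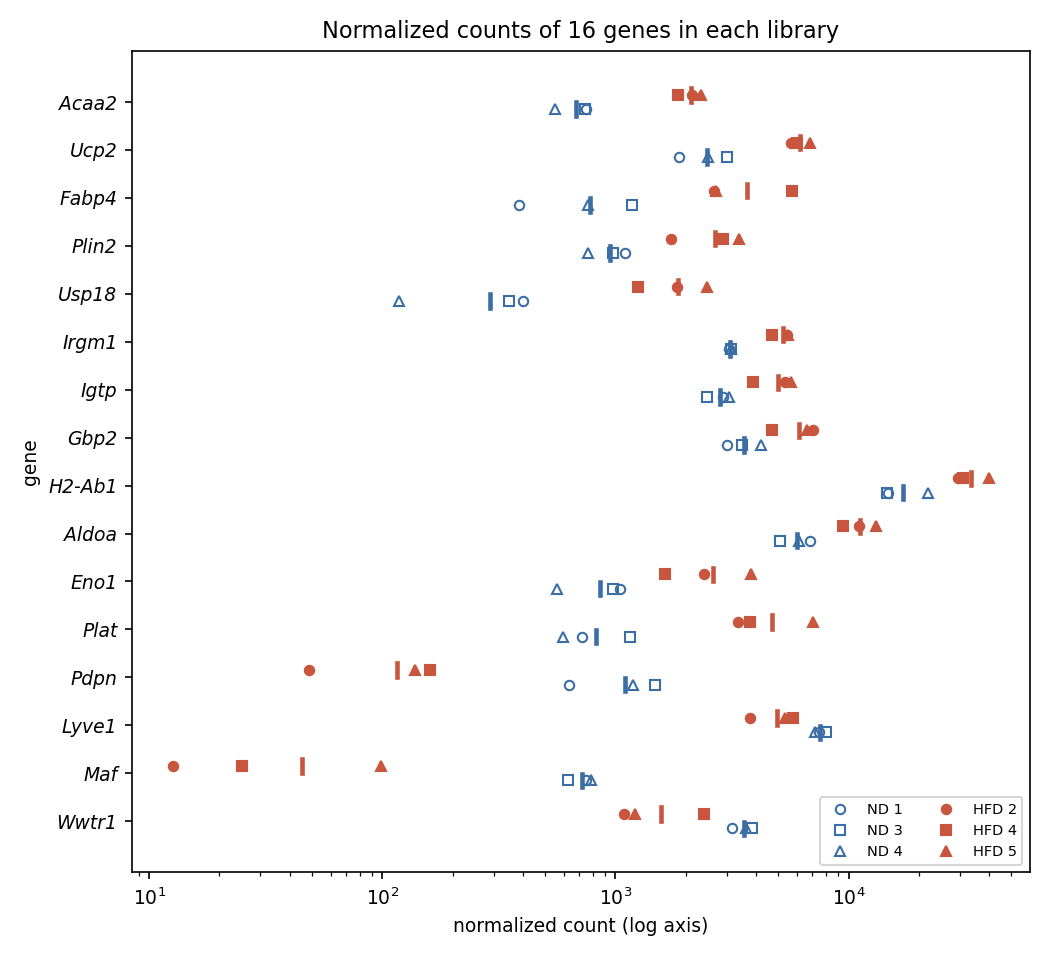
Normalized counts of 16 genes in each of the 6 libraries on a log axis, with ND libraries as open blue and HFD libraries as filled red symbols and vertical marks at the group means (n = 3). The 16 genes were selected from the named genes, of which others, such as Tap2, Pkm, Prox1 and Ccl21a, had overlapping values. For each of the 16 genes the ND and HFD values do not overlap, so the figure does not show how common such separation is. None of the 16 passed limma over all genes.

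Markers of lymphatic endothelium fell as a group in HFD by 1.14 log2 units on average, from a mean level of 8.64 ± 0.63 to 7.50 ± 1.43 (SD, n = 3), with 8 of 10 genes lower (camera adjusted p = 0.0364, and adjusted p = 0.826 with an estimated correlation). Pdpn, a surface glycoprotein of lymphatic endothelium and of alveolar type I cells, had 1097 ± 430 normalized counts in ND and 115 ± 59.0 in HFD, a log2 fold change of −3.32 ± 0.62. It passed limma adjusted over the list alone (adjusted p = 0.00939) and not over all genes (0.338). Lyve1, a hyaluronan receptor, had 7550 ± 418 and 4955 ± 1040 (−0.63 ± 0.22), again without overlap between the diets. Prox1, the transcription factor of lymphatic identity, and Ccl21a, a lymphatic chemokine with near-identical copies, had log2 fold changes of −2.94 ± 1.39 and −1.88 ± 1.01 with overlapping values, which were −1.82 without ND 4 for Prox1 and −0.80 without HFD 2 for Ccl21a. The list call was lost without ND 3, ND 4 or HFD 2, at adjusted p = 0.0516, 0.126 and 0.273. The mean fall rested largely on HFD 2, which had the lowest level, 6.03, since the mean log2 fold change was −0.41 without HFD 2, against −1.50 without ND 3 and −1.84 without HFD 4. Pdpn lies on chromosome 4 from 143267431 to 143299564 and Lyve1 on chromosome 7 from 110850607 to 110863239.

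Markers of cells outside the endothelium shifted too. Mural genes, those of pericytes and smooth muscle, fell by 1.16 log2 units on average, from 6.25 ± 1.14 to 5.09 ± 0.55 (SD, n = 3), with 13 of 16 lower (camera adjusted p = 0.0414, and adjusted p = 0.826 with an estimated correlation). The call was lost without ND 1, ND 3, HFD 2 or HFD 5, at adjusted p = 0.1099, 0.379, 0.0834 and 0.0591, and the mean log2 fold change was −0.63 without ND 3 and −1.76 without ND 4. Among its genes, Cnn1, a smooth muscle calponin, had 163 ± 142 normalized counts in ND and 2.88 ± 1.74 in HFD, but ND 4, at 3.56, lay among the HFD values. Actg2, a smooth muscle actin, had 3 reads or fewer in each HFD library, and its ND to HFD ratio was 275, with a 95% exact counting interval of 75.6 to 2277. The interval leaves out the spread between mice, as Actg2 had 370 normalized counts in ND 1, 85.5 in ND 3 and 1.19 in ND 4, which lay among the HFD values, and the ratio was 83.4 without ND 1 and 182 without HFD 4. All HFD reads of Actg2 came from HFD 5, so the ratio has no finite value without that library. Rgs5 and Notch3, markers of pericytes, had log2 fold changes of −1.08 ± 0.48 and −2.04 ± 1.10, the latter −1.03 without HFD 4. Epithelial genes fell by 1.05 log2 units on average, with 14 of 19 lower (camera adjusted p = 0.0414, and adjusted p = 0.826 with an estimated correlation), but their level was 9.70 in ND 3 against 5.61 to 7.10 in the other 5 libraries. Without ND 3 the mean log2 fold change of this list was −0.0038 at an adjusted p of 0.902, and without HFD 2 it was −0.58 at 0.273, against −1.71 without ND 1. Sftpc, a surfactant protein of alveolar type II cells chosen for mention after its values were seen, had 70918 normalized counts in ND 3 and 111 to 1195 in the others. Sftpa1 and Sftpb, further surfactant proteins, had ND means of 1900.1 ± 3019 and 196 ± 321, and Sftpb had 3 reads or fewer in each HFD library (ND to HFD ratio 153, interval 65.1 to 473). Most of the ND reads of Sftpb came from ND 3, with 567 normalized counts against 20.1 in ND 1 and 1.19 in ND 4, which lay among the HFD values, and the ratio was 7.80 without ND 3, 275 without HFD 2 and 101 without HFD 4. Hopx and Cldn18, which alveolar cells express, had log2 fold changes of −1.24 ± 0.48 and −0.95 ± 0.46, the latter −0.51 without ND 3. Adjusted over the list alone or over all genes, 0 mural and 0 epithelial genes passed limma.

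**Figure D3:**
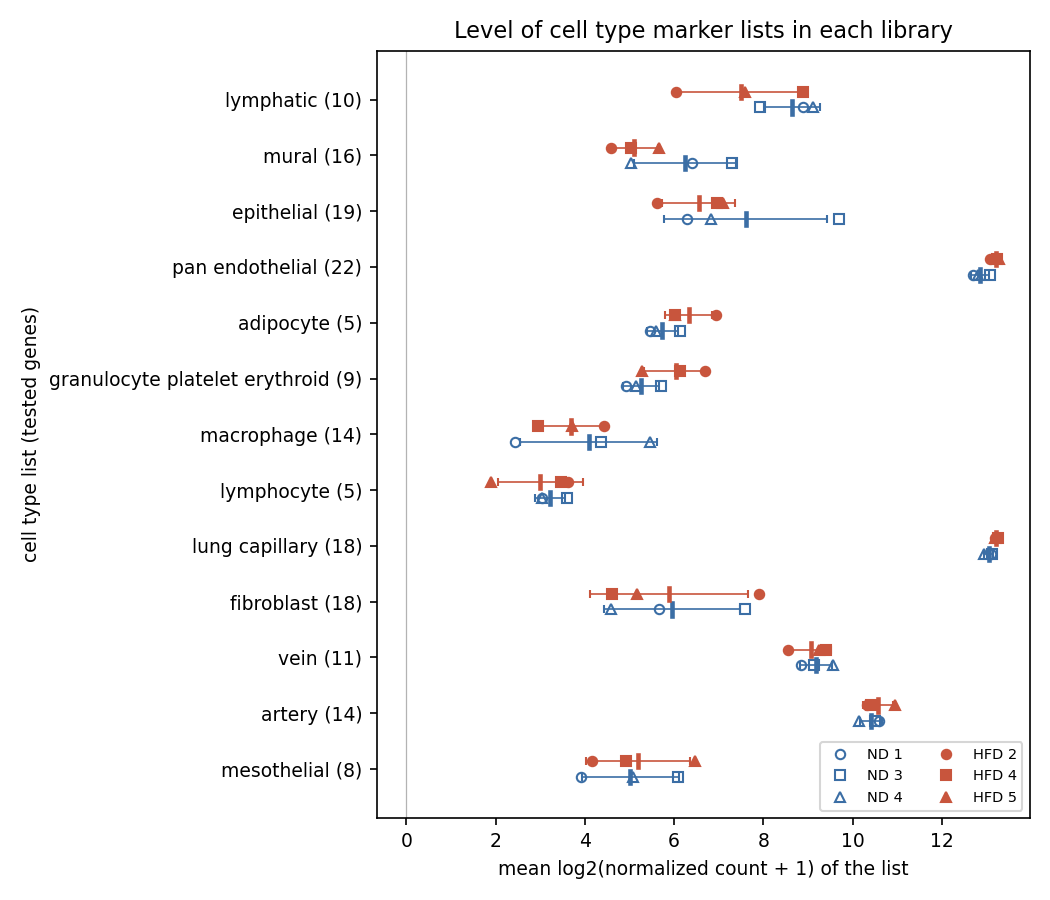
Mean log2(normalized count + 1) of 13 cell type marker lists in each of the 6 libraries, with the number of tested genes after the name. Open blue symbols are ND and filled red symbols HFD libraries, vertical marks are group means and horizontal bars are 1 SD (n = 3). The pan endothelial and lung capillary lists are highest, at 12.69 to 13.28, and the epithelial level of ND 3 is 9.70.

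YAP-target genes, which respond to cell stretch and contact, fell as a group by 0.49 log2 units on average, with 18 of 25 lower (camera adjusted p = 0.0466, and adjusted p = 0.826 with an estimated correlation). Ctgf (Ccn2 in GENCODE), a matricellular protein, had 80.2 ± 13.7 normalized counts in ND and 9.40 ± 4.78 in HFD, a log2 fold change of −3.09 ± 0.81. Wwtr1, which encodes the YAP partner TAZ, had 3556 ± 365 and 1569 ± 721 (−1.27 ± 0.35). Nt5e, an ectonucleotidase, had −1.62 ± 0.75, and Foxf2, a forkhead factor of mesenchyme with 3 reads or fewer in each HFD library, had an ND to HFD ratio of 14.2 (95% exact counting interval 5.72 to 45.7), which was 8.22 without ND 4. The YAP call was lost without ND 3, ND 4, HFD 2 or HFD 5, at adjusted p = 0.416, 0.122, 0.211 and 0.163. Its mean log2 fold change was −0.12 without ND 3, −0.82 without ND 1 and −0.13 at a minimum mean of 50, where the call was lost too (adjusted p = 0.186), and ND 3 was the library with the high epithelial level. All 13 mitochondrially encoded genes were lower in HFD, by 0.36 log2 units on average (camera adjusted p = 0.0414, and adjusted p = 0.826 with an estimated correlation). The respiratory complex I subunits mt-Nd1, mt-Nd4, mt-Nd3 and mt-Nd6 had log2 fold changes of −0.41 ± 0.22, −0.35 ± 0.23, −1.004 ± 0.72 and −0.36 ± 0.29. Those of mt-Nd1, mt-Nd4 and mt-Nd6 were −0.24, −0.17 and −0.22 without ND 1 and −0.22, −0.16 and −0.11 without HFD 5, and mt-Nd4 and mt-Nd6 had −0.53 and −0.56 without ND 4. Mitochondrial genes took 3.15% ± 0.455 of the normalized counts in ND and 2.46% ± 0.569 in HFD (SD, n = 3). The mitochondrial call was lost without ND 1, ND 3 or HFD 5, at adjusted p = 0.462, 0.0788 and 0.455, and the mean log2 fold change was −0.17 without ND 1 and −0.16 without HFD 5. With sample quality weights it was −0.24 at an adjusted p of 0.190. Nuclear genes of oxidative phosphorylation did not pass (camera adjusted p = 0.750, mean log2 fold change 0.03, median −0.07). In both the YAP and the mitochondrial list 0 genes passed limma, adjusted over the list alone or over all genes.

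The 5 genes of smallest p in each direction, taken over all genes with a symbol other than a clone name and a mean of at least 50 normalized counts, did not pass (limma adjusted p = 0.276 to 0.338), and their ND and HFD values did not overlap. Sae1, a subunit of the enzyme that activates SUMO for attachment to proteins, had 341 ± 72.1 normalized counts in ND and 2529 ± 469 in HFD, a log2 fold change of 2.89 ± 0.33. Inpp5b, an inositol polyphosphate phosphatase, had 548 ± 213 and 2982 ± 226 (2.53 ± 0.38), and Adal, a deaminase, had 4.12 ± 2.67 and 273 ± 128 (5.79 ± 0.86). Tcf19 and Pcdhga3 had 3 reads or fewer in each ND library. Their HFD to ND ratios were 159 (95% exact counting interval 54.2 to 774) and 104 (35.5 to 508), the latter 202 without ND 3, and 44.9% of the exonic bases of Pcdhga3 are shared with other genes of its protocadherin cluster, so its value is uncertain. In the other direction, Maf, a transcription factor, had 722 ± 83.4 and 45.4 ± 46.5 (−4.46 ± 0.79). Btnl9, a butyrophilin-like surface protein, Zfp128, a zinc finger protein, and Panx1, a membrane channel, had 3 reads or fewer in each HFD library. Their ND to HFD ratios were 221 (94.4 to 683), 159 (54.1 to 777) and 63.5 (28.8 to 174), and that of Zfp128 was 105 without HFD 4 and 297 without HFD 5. Pdpn, given above among the lymphatic genes, was the remaining one. Sae1 lies on chromosome 7 from 16320234 to 16387806, Tcf19 on chromosome 17 from 35512734 to 35516824, Maf on chromosome 8 from 115682942 to 115707794 and Btnl9 on chromosome 11 from 49165585 to 49187159.

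Endothelial identity was high in all libraries. The pan-endothelial list had a mean level of 12.86 ± 0.20 in ND and 13.21 ± 0.10 in HFD (SD, n = 3), with the ND libraries at 12.69 to 13.09 and the HFD libraries at 13.09 to 13.28, and a camera adjusted p of 0.0566 that did not pass. Egfl7 and Clec14a, endothelial surface and secreted proteins, passed limma adjusted over the list alone (adjusted p = 0.0338 for both) and not over all genes (0.418 and 0.425), with log2 fold changes of 1.14 ± 0.25 and 0.84 ± 0.19. Egfl7 shares 11.2% of its exonic bases with other genes. Icam2 had a log2 fold change of 0.49 ± 0.17, Pecam1 0.35 ± 0.15, Vwf 0.31 ± 0.32 and Cav1 0.41 ± 0.22, against −0.38 ± 0.19 for Cdh5. Leaving out a library took Vwf to 0.09 (ND 1), 0.61 (ND 3) and 0.13 (HFD 4), Cav1 to 0.17 (ND 3) and Cdh5 to −0.22 (HFD 5). Nos3, the endothelial nitric oxide synthase, had 165 ± 72.1 normalized counts in ND and 182 ± 173 in HFD. Its log2 fold change of −1.42 ± 1.72 rested on the value of 1.94 in HFD 2 and was 0.74 without that library, against −2.29 without HFD 4 and −2.70 without HFD 5, and 32.3% of its exonic bases are shared with other genes. The adhesion molecules Vcam1 and Icam1 had log2 fold changes of 0.55 ± 0.62 (0.03 without ND 4 to 1.09 without HFD 2) and 0.69 ± 0.47 (0.27 without ND 1 to 1.18 without ND 3), and the inflammation and adhesion list did not pass (camera adjusted p = 0.750).

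Other lists did not pass camera, 30 in all, at adjusted p = 0.0566 to 0.948, but 4 of them held a gene not yet named that passed limma adjusted over the list alone, while 0 passed over all genes. Plat of the coagulation list, tissue plasminogen activator, had 822 ± 293 normalized counts in ND and 4713 ± 2012 in HFD, a log2 fold change of 2.50 ± 0.40 (adjusted over the list alone, adjusted p = 0.00777). Kif20a of the cell cycle list, a mitotic kinesin with 29.3% of its exonic bases under Cdc23 on the opposite strand, had 6.45 ± 1.501 and 160.5 ± 98.6 (4.24 ± 0.84 and 0.0431). Ppp1r15a of the unfolded protein list, which directs dephosphorylation of eIF2α, had 3341 ± 1286 and 11849 ± 3991 (1.84 ± 0.38 and 0.0460). Hspa8 of the immediate early list, a cytosolic chaperone, had 8122 ± 1673 and 18678 ± 4822 (1.19 ± 0.24 and 0.0433). Mki67, a proliferation marker, had 3.40 ± 0.958 and 109 ± 158, a log2 fold change of 3.07 ± 1.52 with overlapping values, which was 1.56 without HFD 4. Of the other cell types, fibroblast genes had a mean level of 5.94 ± 1.53 in ND and 5.89 ± 1.76 in HFD, mesothelial genes 5.02 ± 1.09 and 5.19 ± 1.17, adipocyte genes 5.73 ± 0.35 and 6.32 ± 0.54, and granulocyte, platelet and erythroid genes 5.25 ± 0.40 and 6.04 ± 0.72 (SD, n = 3). None of these 4 lists passed camera, at adjusted p = 0.750, 0.784, 0.559 and 0.613.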

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

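Limma-voom and thinning to equal depth were chosen only after the result was seen, and the other settings were fixed before the data were examined. Limma called 0 genes under each setting of scaling, filter, pseudocount, weights, threshold and left-out library, except for 1 gene, Tcf19, called without the trend. DESeq2 called 272 and edgeR and limma-voom 0. In simulated counts with the spread of these libraries DESeq2 called 105 unchanged genes and limma 0, and in the 9 other splits of the libraries DESeq2 called 68 to 136 genes. Of 9 lists past the threshold in camera, the count was 3 with equal column totals, 4 with quantile normalization, 3 with sample quality weights, 0 with an estimated correlation, 0 in fry, 8 at a minimum mean of 1, 7 with no filter and 6 at a minimum mean of 50. Leaving out a library gave 4 (without ND 3 or HFD 5) to 8 (without HFD 4) lists, each from fewer samples. The interferon and fatty acid lists kept their call in 18 of 19 alternatives, all but the estimated correlation, against 14 for lymphatic, 11 for epithelial and mitochondrial, 10 for mural and glycolysis, 9 for antigen presentation and 8 for YAP targets, and none turned its direction. The robust fit and the fit without trend are among the 19 but enter only the gene test, so they could not change a list call. The fry test is not among the 19, and it called neither leading list, at adjusted p = 0.321 for interferon and 0.0583 for fatty acid use. The diets were fully apart in 2 of 15 identity, other-cell and quality lists (pan-endothelial and lung capillary), in 2 (without ND 1) to 5 (without ND 3) with a library left out, where smaller groups separate more easily, while camera called 4. The principal component most correlated with diet, the second at the leading settings, held 21.9% of the variance. In the alternatives the component most correlated with diet held 22.96% over the 500 most variable genes and 22.4% at a pseudocount of 5. Of 63 named genes, 2 changed sign in 4 of 1318 alternatives. The Angptl4 log2 fold change was −0.026 without HFD 5 and 1.88 without HFD 4. The Nos3 log2 fold change was 0.74 without HFD 2, −2.70 without HFD 5, 0.083 in edgeR and 0.048 in DESeq2. The last pair has the direction of the group means, 165 normalized counts in ND and 182 in HFD. The limma value of −1.42 averages log2 values, in which the 1.94 of HFD 2 weighs heavily. DESeq2 called 25 of the named genes, among them Acaa2, Ucp2, Fabp4, Plin2, Usp18, Pdpn, Plat, Sae1 and Inpp5b. No paired analysis was possible because the diets share 1 mouse number, which names different animals. The deposited values are normalized, so edgeR was not made the leading test, and edgeR without a filter or with DESeq2 size factors was not run. Thinned to the depth of the shallowest library, 0 genes and 8 lists were called. At the spread between these libraries limma recovered 14.9% of simulated 4-fold changes.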

Other observations

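The tests of other splits for limma and for camera, of read sampling, of depth, of single libraries, of ND 3 and of other cell types were chosen only after the result was seen, as were the genes and lists described next. Read in either direction, which asks whether the genes of a list change without asking for a common sign and without comparing them with other genes, fry passed 4 of 39 lists. These were Notch signalling (adjusted p = 7.41e-05), cell junctions (0.00533), artery (0.0136) and coagulation (0.0136). In the Notch list, the ligand Dll4, a marker of tip and arterial cells, had 1774 ± 252 normalized counts in ND and 772 ± 105 in HFD (SD, n = 3), a log2 fold change of −1.20 ± 0.29 (SE). The Notch effector Hes1 had −0.57 ± 0.23 and the modifier Lfng −0.87 ± 0.47, while Nrarp, a feedback inhibitor, had 2.73 ± 3.84 and 39.2 ± 23.5 normalized counts. Of its 18 tested genes, 5 were non-overlapping and lower and 1 non-overlapping and higher, and the camera adjusted p was 0.613. Among junction genes, Gja4, Jam2, F11r and Ocln had log2 fold changes of 0.91 ± 0.25, 1.07 ± 0.30, 0.91 ± 0.26 and 0.65 ± 0.21. The adaptor Cgnl1, at −1.84 ± 0.55, and Tjp1, at −0.36 ± 0.19, had the opposite sign. No gene named here passed limma over all genes.

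The unfolded protein list did not pass camera (adjusted p = 0.249), with 20 of 28 genes higher, a median log2 fold change of 0.15 and list levels that overlapped between the diets. Of its genes, 6 were non-overlapping and higher and 1, Slc7a11, non-overlapping and lower (−0.62 ± 0.71, and −0.39 without HFD 5). Hspa5, the main chaperone of the endoplasmic reticulum, had 6839 ± 1505 normalized counts in ND and 16378 ± 6185 in HFD, a log2 fold change of 1.22 ± 0.30. Creld2 and Pdia6 had 1.19 ± 0.34 and 0.68 ± 0.20. Genes of fatty acid synthesis went both ways, with 3 non-overlapping and lower and 2 non-overlapping and higher of 21 tested. The desaturases Scd1 and Scd2 and Dgat2, which makes triglyceride, had log2 fold changes of −4.69 ± 1.76, −1.24 ± 0.44 and −1.23 ± 0.46, and the elongases Elovl5 and Elovl1 had 0.56 ± 0.20 and 0.73 ± 0.27. The Scd1 value was −2.58 without HFD 5. The cell cycle list did not pass camera (adjusted p = 0.0802), with a mean level of 5.11 in HFD 2, 5.34 in HFD 4 and 6.96 in HFD 5 against 4.90 to 4.95 in ND. Its gene Ccnb2 had 45.6, 13.7 and 367 normalized counts in these HFD libraries and 0 to 1.18 in ND.

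With 6 libraries there are 10 splits of 3 against 3, too few for a share under 0.05. Limma called 0 genes in the real split and in each other, so 10 of 10 gave as many, and at an unadjusted p under 0.05 the real split had 1240 genes and the highest other 903. Camera called 9 lists in the real split and at most 6 in another, so 1 of 10 gave as many, and the interferon list also passed in 1 other split, ND 1, HFD 2 and HFD 5 against the rest (adjusted p = 0.0234). DESeq2 called 272 genes in the real split and at most 136 in another, again 1 of 10. For the 4 lists of the test in either direction, 2 of 10 splits gave as many, the other being ND 1, ND 4 and HFD 4 against the rest, also with 4.

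The higher levels of the fatty acid and interferon lists in HFD could come from the deeper HFD libraries, from a single library or, for fatty acid genes, from fat cells. With reads thinned to equal depth the larger camera adjusted p of the lists was 0.0364 and the mean fold changes were at least 0.981 of their size. Thinned reads were rescaled, which leaves the expected normalized value of each gene unchanged, so little change could follow at these list levels. Thinning shows only that fewer reads of the same libraries kept the shift, and depth as a source stays open. The largest adjusted p without any 1 library was 0.0492, which argues against a single library, although both calls were lost with an estimated correlation. Of the adipocyte genes outside the fatty acid list, 6 had a median log2 fold change of −0.081 (SD 0.591). The highest of them, Plin1, had 15.2 normalized counts in ND and 14.6 in HFD beside 3681 for Fabp4. This argues against fat cells as far as genes of such low counts can show. The adipocyte markers Adipoq, Cidec, Cidea, Retn and Cfd were not among the deposited genes and could not be checked. A response of the endothelium to the diet stays open as a hypothesis that was not tested apart from these, and differences between the mice or their cultures unrelated to diet stay open too. The pan-endothelial and lung capillary lists were also higher in each HFD library than in each ND library, by 0.34 and 0.16 log2 units on average. Whether the make-up of the cells carried the shift of the fatty acid and interferon lists was not tested.

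Many genes with a high mean had almost no reads in some library, namely 1305 of 11515 genes with a mean of at least 50 normalized counts, 565 of 9886 at 100, 36 of 7049 at 300 and 1 of 3535 at 1000. Poisson sampling of reads predicts 0 such genes where 565 were found, which argues against read sampling alone for these 565. That outcome already followed from the pairs of libraries, which all differed by more than sampling noise, with a chi-square per degree of freedom of 96.2 to 231. It does not tell differences between the mice apart from noise that arose before sequencing. At a mean of at least 50, no single library held most of the gene and library pairs with 3 reads or fewer, since the largest share was 22.5% in ND 1 and the lowest 9.77% in HFD 5, which argues against one poor library. Of 140 genes with a mean of at least 50 and near 0 in exactly 3 libraries, 16 split by diet, 10 of them near 0 in ND and 6 in HFD, against 8 to 22 with a median of 12 in the other splits, so switching by diet cannot be told apart from the rest with 16 genes inside that range. Loss of rare transcripts before amplification from 500 cells may be a source, which these values do not test, and 123 of the 272 DESeq2 genes had 3 reads or fewer in some library.

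The lower mural and epithelial lists in HFD may rest on ND 3, which had the highest level of both, whereas for the lower lymphatic list ND 3 had the lowest ND level. Without ND 3 the epithelial list had a mean log2 fold change of −0.0038 (SE 0.64), in line with that library alone carrying the shift. For the mural list the value was −0.63 (SE 0.65), which leaves open whether ND 3 alone accounts for it, and for the lymphatic list it was −1.50 (SE 1.07), a fall no smaller than with all 6 libraries but within 2 standard errors of 0, while it was −0.41 without HFD 2. Fewer cells of every other type in HFD cannot be told apart from other sources, since fibroblast, mesothelial, macrophage, lymphocyte and granulocyte lists differed by −0.06, 0.16, −0.39, −0.22 and 0.78 log2 units, with the largest ratio of difference to standard error at 1.65. A loss of lymphatic cells or of their genes with diet stays open and was not tested.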
